A study of Mus musculus with 2 samples.

How the data were processed

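Trimethylation of histone H3 at lysine 27 (H3K27me3), the mark laid down by Polycomb repressive complexes, was mapped by chromatin immunoprecipitation and sequencing in the facial prominences of mouse embryos at day 13.5. Per the labels, the tissue came from the B6NCrl strain, male and female embryos were pooled, and there were 2 biological replicates, each made of 2 technical replicates. The replicates formed 1 group, with no treatment, stage or tissue to compare, so the design allowed descriptions of where the mark lay and comparisons between sets of genes, chromosomes and replicates. The labels did not say how many embryos each pool held or in what proportion of the sexes.

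The authors deposited 4 peak lists on the mm10 assembly, 1 for each replicate, 1 called on both replicates together (the pooled list) and 1 of replicated peaks. According to the descriptions deposited with the samples, the list of replicate 1 was made from its filtered alignments and 1 further input, and that of replicate 2 from its alignments and 2 further inputs, 1 of which replicate 1 also used. What the further inputs held was not stated, although the labels named a control experiment. The replicated list was derived from the pooled list and both replicate lists. The aligner, the peak caller, their versions and the rule for calling a peak replicated were not given in the sources used here. Each deposited peak carried an enrichment, a linear ratio given as the signal value of the narrowPeak format, and a −log10 q within its own list. What the enrichment was relative to was not stated. Both values were the authors' own and served here to describe, rank or filter the peaks of a list. Enrichment in the replicated list was also compared between gene lists by permutation, and that of X peaks between the replicates by bootstrap, although each replicate list has its own unstated background. The lists gave no read counts, so the sequencing depth of each sample was unknown and no counting interval could be set on an enrichment. A gene without a peak was therefore a gene without a call at that unknown depth.

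Genes were the 21728 protein-coding genes of the GENCODE vM21 annotation (GRCm38, the same assembly as mm10) on the 19 autosomes and the X chromosome. No list held a peak on another sequence. A gene was called marked when a replicated peak overlapped the 2-kb window reaching 1 kb either side of its 5′ end by at least 1 bp. The 5′ end was the outermost annotated start of the gene. For each gene the percentage of the window covered by the peaks of each replicate was computed, and its mean and SD over the 2 replicates were given. Coordinates were 1-based. The enrichment quoted for a gene was that of its strongest replicated peak overlapping the window. Such a peak could reach beyond the window and could be shared by neighbouring genes. Replicated peaks separated by gaps of up to 3 kb were joined into domains, and domains of at least 10 kb were called wide. The observed/expected CpG ratio of each window was computed from the RefSeq GRCm38 sequence.

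Peaks of a replicate were shared when the other replicate's peaks covered at least 50% of their length. The chance level came from 1000 random circular shifts of the peaks along their chromosomes, or 100 for reciprocal overlap and for the annotation of peak positions. Lists of genes were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 48 lists at a false discovery rate of 0.05. Of these, 18 were lists of named genes and 30 were families defined by the pattern of their symbols. The covered share of the X chromosome was ranked among the 20 chromosomes, an exact permutation whose smallest p is 0.05. Medians were compared by permutation with 100000 resamples, or 2000 for alternative settings. Genes are not independent replicates, and neighbours can share a peak, so these tests describe the sets in these samples. Shares of genes or peaks were given with 95% Wilson intervals, which cover counting error only.

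The genes named in the text followed a rule set together with the gene lists, the tests and all alternatives except the omission of chromosome X before the data were examined. It took from each list the 4 marked members with the highest mean covered share, ties broken by enrichment, and the first 2 unmarked members alphabetically. It also took the 2 highest-covered marked members of each family, genes with a 5′ end in the 10 widest domains, and the 5 genes with the largest coverage difference between replicates in each direction. Other genes named, where few members stood apart from their list, were chosen after their values were seen.

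The alternatives were a stricter list (−log10 q of at least 3), either replicate alone, the pooled list, windows of 2.5 or 0.5 kb either side, at least 50% of the window covered, any annotated transcript start, neighbours within 100 kb counted once, only promoters with a CpG ratio of at least 0.6, other overlap rules, the 20000 strongest peaks and other gaps for domains. The list test and the overlap were tested on simulated data. In 100 simulations over 21728 genes, 100% of lists of 40 genes raised by an odds ratio of 8 were called, as were 0.7% of unchanged lists. The simulated members were drawn at random and marked independently. These rates therefore do not cover lists of neighbouring genes that share peaks, or smaller lists. In the overlap simulation 40% of peaks were kept in place with identical edges, and 39.2% was recovered after correction for the share found after shifts. The shares given in the results carry no such correction. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.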

Results

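The facial prominences are the swellings of the embryonic head, filled largely with neural crest-derived mesenchyme and covered by epithelium, that form the face and jaws. Peaks of H3K27me3, a histone mark of Polycomb-repressed chromatin, were available for 2 biological replicates of this tissue at embryonic day 13.5. Replicate 1 had 118660 peaks covering 59.4 Mb, 2.25% of the chromosomes, and replicate 2 had 115716 peaks covering 58.0 Mb, or 2.20%. The pooled list held 133901 peaks and the replicated list 65365 peaks over 55.7 Mb, with a median width of 467 bp and a widest peak of 79666 bp. Median enrichment was 2.69 in replicate 1, 2.77 in replicate 2 and 2.80 in the replicated list, where the strongest peak reached 19.7. The depth behind these calls was unknown, since the lists held no read counts.

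The first comparison asked how far the replicates placed the mark at the same positions and genes. Promoters of several developmental regulators were covered throughout in both. The windows of Hoxc11, a Hox gene of posterior body identity, of Shh, a secreted signal of facial and limb patterning, and of Neurog3, a neurogenic and endocrine transcription factor, were covered over 100% ± 0 (SD, n = 2). The genes that differed most in one direction all lay on the X chromosome. Apex2, a DNA repair endonuclease gene, was covered over 0% in replicate 1 and 65.1% in replicate 2, Plxnb3, a semaphorin receptor gene, over 15.1% and 82.8%, and Xkrx over 39.1% and 94.1%. Prps1, a nucleotide synthesis gene, had 7% and 67.3%, and Pls3, an actin-bundling protein gene, 14.1% and 68.3%. The 5 genes that differed most the other way were autosomal. Among them were Gsc, a homeobox gene of the jaw mesenchyme, with 89.1% in replicate 1 and 18.6% in replicate 2, Ndst3 with 78.1% and 0%, and Timp4 with 74.3% and 11.2%. Dnah9 had 76.3% and 13.1%, and A230072I06Rik 83.1% and 15.9%.

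Across all protein-coding genes, 5399 had a peak in the window in replicate 1, 5085 in replicate 2 and 4535 in both. On the X chromosome 16 genes had one only in replicate 1 and 70 only in replicate 2, against 848 and 480 on the autosomes. Window coverage correlated between the replicates across genes with Pearson's r = 0.968 and Spearman's rho = 0.879, values across genes, which are not independent replicates. Most genes had no peak in either replicate and count as agreement in these values. Agreement was lower at the peaks. Of the replicated peaks 75.4% overlapped a peak of both replicates, and across these log2 enrichment correlated with Pearson's r = 0.740 and enrichment with Spearman's rho = 0.515. Of the peaks of replicate 1, 38.8% were shared with replicate 2, against a mean of 2.61% after circular shifts. For replicate 2 the share was 40.8%, against 2.54%. Both permutation p-values were 0.000999, the smallest that 1000 shifts can give. The lists of replicates 1 and 2 reached down to a −log10 q of 0.467 and 0.490. The shares changed with the threshold and the overlap rule. In replicates 1 and 2, 45.5% and 45.6% were shared at a −log10 q of at least 3. For the 20000 strongest peaks of each the shares were 54.7% and 58.1%, and reciprocal overlap gave 26.2% and 26.9%. On the X chromosome 62.0% of the peaks of replicate 1 but 31.8% of those of replicate 2 were shared. The replicates had 35.1 Mb in common, 42.6% of their union. Of the pooled peaks 48.8% (95% Wilson interval 48.5 to 49.1%) were in the replicated list, from 10.8% in the weakest quartile by q to 94.9% in the strongest. In the replicated list 59.1% of peaks were at least 50% covered by peaks of each replicate, 17.4% only by replicate 1, 20.3% only by replicate 2 and 3.19% by neither. How the list was derived limits what it adds as a check on the replicates, since it was built from the same calls.

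The next question was which genes carried the mark at their 5′ ends. In total 4700 of 21728 protein-coding genes (21.6%) were marked, and 2978 had at least 50% of the window covered. Nearly all members of the fixed lists of central nervous system, endoderm and kidney, and heart and limb transcription factors were marked, and so were most of the facial mesenchyme list. Of the 48 lists tested, 29 were marked more often than other genes and 9 less often (Fisher's exact test, adjusted p under the threshold). The lists overlap, so these calls are not all separate results. The facial list holds every Dlx gene, for example, and the signalling list most Wnt genes.

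All 39 Hox genes, the homeobox genes that set position along the body axis, were marked (adjusted p = 9.92e-26, Fisher's exact test). Hoxc11 and Hoxc12 reached an enrichment of 13.1, Hoxb13 of 13.0 and Hoxc8 of 12.4, each with the window covered over 100% ± 0 (SD, n = 2). Transcription factors of the central nervous system were marked in 57 of 58 cases (adjusted p = 1.06e-35, Fisher's exact test). Among members covered throughout in both replicates, Neurog3 had the highest enrichment at 19.2. Next came the neuronal differentiation gene Neurod2 at 14.1, the brain and kidney gene Pax2 at 12.1 and the neuronal differentiation gene Neurod1 at 11.8. The exception was Neurod4, at 0% in both replicates. Factors of endoderm and kidney were marked in 23 of 24 cases (adjusted p = 4.96e-14, Fisher's exact test). Members covered throughout included Onecut1 with an enrichment of 11.8, Gata5 with 10.3, Foxa2 with 9.91 and the pancreatic gene Pdx1, whose domain spanned 65107 bp. Hnf4a, a liver regulator, was unmarked, with 9.25% ± 1.91 (SD, n = 2) of its window covered in the single lists. Heart and limb factors were marked in 19 of 20 cases (adjusted p = 1.57e-11, Fisher's exact test), with Lmx1b at 12.9, Pitx1 at 11.7, Irx4 at 11.5 and Nkx2-5 at 10.2, whereas Mef2c was covered over 0%.

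Of 46 transcription factor genes of facial mesenchyme and neural crest, 41 were marked (89.1%, 95% Wilson interval 77.0 to 95.3%, adjusted p = 1.38e-21, Fisher's exact test). Foxf1 (enrichment 12.1), Pitx1 (11.7), the glial and pigment lineage gene Sox10 (8.82) and Dlx4 (8.77) had windows covered over 100% ± 0 (SD, n = 2). The unmarked members were Prrx1, Prrx2, Runx2, Snai2 and Zeb2, known from craniofacial mesenchyme, bone or neural crest. Prrx1 was covered over 10.5% in replicate 1 and 0% in replicate 2, and Prrx2 over 0% in both. Runx2 has further annotated starts, and 5 of its 11 had a replicated peak within 1 kb. The median covered share of the facial list was 76.7% and that of the central nervous system list 100%.

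**Figure D1:**
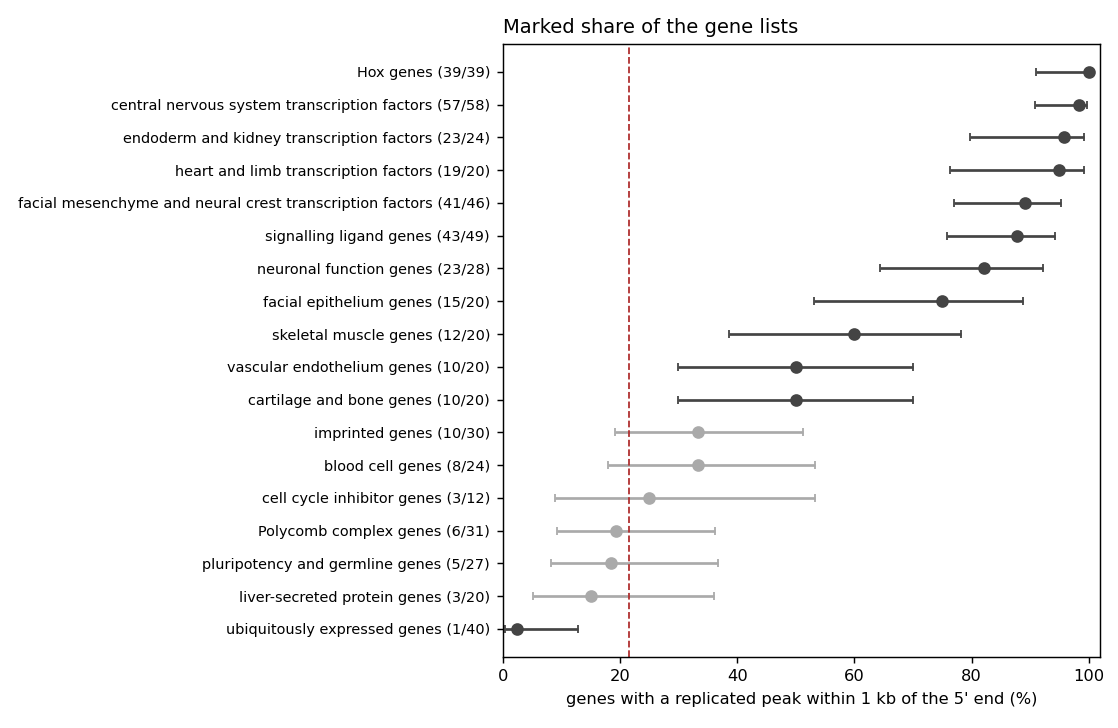
Percentage of genes marked (horizontal axis) in each of the 18 fixed gene lists, with the number marked and tested beside each name; points are shares, bars 95% Wilson intervals, black points lists that passed the test and grey points those that did not. The dashed line is the 21.6% of all protein-coding genes, and Hox genes lie at 100% while ubiquitously expressed genes lie at 2.5%.

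Genes of signalling ligands were marked in 43 of 49 cases (adjusted p = 5.99e-22, Fisher's exact test), with Shh at an enrichment of 14.1, Wnt3a at 12.6, Wnt1 at 12.3 and Wnt7a at 11.9. Bmp5 was covered over 0% and Fgf1 over 0% and 9.80% in the replicates. Among genes of neuronal function 23 of 28 were marked (adjusted p = 5.85e-11, Fisher's exact test). The neurofilament gene Nefh had an enrichment of 13.4, Chat, the acetylcholine synthesis enzyme, 12.7, Elavl3 12.5 and the vesicular GABA transporter gene Slc32a1 11.6. Gad1, a GABA synthesis gene, was covered over 27.8% in replicate 1 and 0% in replicate 2 and was unmarked, like Elavl4.

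Genes of tissues present in or near the face were marked in part. In the facial epithelium list 15 of 20 were marked (adjusted p = 1.57e-06, Fisher's exact test), among them Foxe1 (enrichment 8.72), the splicing factor gene Esrp1 (7.71), the E-cadherin gene Cdh1 (6.81) and Krt8 (6.30). The unmarked members were Elf3, Trp63, a master regulator of stratified epithelium, and the basal keratin genes Krt5, Krt14 and Krt15. Skeletal muscle genes were marked in 12 of 20 cases (adjusted p = 0.000349, Fisher's exact test). Members covered throughout included the myogenic determination gene Myod1 (enrichment 13.0), Lbx1 (10.7), the actin gene Acta1 (9.43) and Msc (7.73). Actc1 and Myh3, which encode contractile proteins, were unmarked, with 6.68% ± 9.44 and 10.8% ± 15.3 of the window covered (SD, n = 2). Cartilage and bone genes were marked in 10 of 20 cases (adjusted p = 0.00631, Fisher's exact test), with Ihh at 11.5, Comp at 8.40, the aggrecan gene Acan at 5.94 and Col9a2 at 4.70, while Bglap and Col10a1 were covered over 0%. Vascular endothelial genes were also marked in 10 of 20 cases (adjusted p = 0.00631, Fisher's exact test), with Sox18 at 10.2, Cldn5 at 8.55, Sox7 at 8.30 and Sox17 at 8.17, while Cdh5 and Ecscr were covered over 0%.

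Lists that did not pass the test were those of blood cells (8 of 24 marked), imprinted genes (10 of 30), cell cycle inhibitors (3 of 12), Polycomb complex genes (6 of 31), pluripotency and germline genes (5 of 27) and liver-secreted proteins (3 of 20), with adjusted p-values of 0.240, 0.144, 0.779, 1, 0.854 and 0.665 by Fisher's exact test. Single members of some of these lists were nevertheless covered throughout, though none of the Polycomb complex or liver-secreted protein genes was. Gata2, of blood stem cells, had an enrichment of 11.3, the imprinted thyroid hormone deiodinase gene Dio3 13.7, and Pou5f1, of pluripotent cells, 6.89. Cdkn2a and Cdkn2b, neighbouring inhibitors of the cell cycle, had 8.23 and 8.21 and lay in a single domain of 50.3 kb. Among 40 ubiquitously expressed genes 1 was marked (adjusted p = 0.00227, Fisher's exact test), the glycolytic gene Pgk1 on the X chromosome, covered over 25.9% in replicate 1 and 51.3% in replicate 2.

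Families defined by symbol were tested alongside the lists. Every tested member of the Pax (9), LIM homeobox (8), Nkx (14), Dlx (6) and Irx (6) families was marked, with adjusted p-values from 1.55e-09 to 0.000182 by Fisher's exact test. Wnt genes were marked in 18 of 19 cases (adjusted p = 5.85e-11), Fox genes in 30 of 44 (1.58e-10), Sox genes in 14 of 19 (4.63e-06), Fgf genes in 15 of 22 (8.83e-06), Tbx genes in 10 of 13 (6.35e-05), POU genes in 10 of 15 (0.000349), Gata genes in 5 of 6 (0.00328) and Six-family genes in 4 of 6 (0.0284), all by Fisher's exact test. Among genes of excitable cells, 74 of 93 potassium channel genes (adjusted p = 1.53e-31) and 35 of 44 GABA and glutamate receptor genes (adjusted p = 2.50e-15, Fisher's exact test) were marked, with Kcnk9 at 15.4 and Gabra5 and Grik3 at 13.5. Collagens (21 of 44, adjusted p = 0.000218), claudins (10 of 23, 0.0249) and solute carriers (114 of 342, 1.57e-06) were also marked more often than other genes by Fisher's exact test. Examples were Col15a1 with an enrichment of 8.13, Cldn7 with 11.1 and the vesicular acetylcholine transporter gene Slc18a3 with 12.7. The window of Slc18a3 overlaps that of Chat, which had the same enrichment, so these are not separate observations.

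Families marked less often included the receptors of the nose. Of 1134 olfactory receptor genes 12 were marked (1.06%, adjusted p = 5.14e-101), and of 330 vomeronasal receptor genes 0 (upper 95% Wilson bound 1.15%, adjusted p = 1.36e-34, Fisher's exact test). Olfr95 was covered over 53.6% ± 9.90 and Olfr1342 over 43.6% ± 15.2 (SD, n = 2). Zinc finger genes named Zfp were marked in 30 of 394 cases (adjusted p = 2.46e-13, Fisher's exact test), with Zfp853 and Zfp536 covered throughout at enrichments of 9.97 and 8.81. Defensins (1 of 64, Defb25, adjusted p = 1.07e-05), histones (2 of 68, Hist3h2ba and Hist3h2a, 4.40e-05), serpins (2 of 61, Serpina7 and Serpina3n, 0.000202) and NADH dehydrogenase genes (1 of 37, Ndufa4l2, 0.00320) followed, by Fisher's exact test. Both histone calls were small. Hist3h2ba was covered over 12.3% ± 2.12 (SD, n = 2). Hist3h2a was covered over 6.70% in replicate 1 and 0% in replicate 2, and its replicated peak had a −log10 q of 1.32. The symbol pattern of the histones takes core and linker histone genes alike. Ribosomal protein symbols were marked in 6 of 101 cases (adjusted p = 5.37e-05, Fisher's exact test). Of those, Rps6ka3, Rps6ka4 and Rps6kl1 encode kinases caught by the symbol pattern, Rpl36a and Rps4x are X-linked, and Rpl3 was marked at 1 of its 7 annotated transcript starts. Keratins (11 of 49, adjusted p = 0.881), protocadherins (16 of 68, 0.720), proteasome subunits (4 of 40, 0.103) and cytochromes P450 (14 of 99, 0.103) did not pass Fisher's exact test. In replicate 1 alone, without replicate 2, keratins (40.8% marked, adjusted p = 0.0162) passed above and proteasome subunits (10%, adjusted p = 0.0331) below by Fisher's exact test. Krt8, Pcdh1, Psmb8 and the retinoic acid hydroxylase gene Cyp26a1 were among the marked members and covered throughout.

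When neighbouring genes in the same state were counted once, 19 lists stayed above. The calls for cartilage and bone, skeletal muscle, endothelium, Dlx, Six-family, Gata, POU, collagens, claudins, solute carriers, defensins and histones were lost. Neighbours were counted once among the other genes too, which raised the marked share of those genes. For the lists above, a lost call need therefore not mean that the members were neighbours. The cartilage and bone call was also lost with the stricter list (adjusted p = 0.180), with at least 50% of the window covered (0.0584), as was that for NADH dehydrogenase genes (0.0656), and among CpG-rich promoters (0.0698), as were those for skeletal muscle, Dlx, Six-family, claudins, vomeronasal receptors and serpins, all by Fisher's exact test. The CpG-rich setting kept only the members with such promoters, so lists were smaller there.

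The widest stretches of the mark were examined as domains. All 4 Hox clusters were among the 5 widest. The HoxC domain on chromosome 15 (102884575 to 103126225) spanned 241.7 kb and held the 5′ ends of 9 genes, Hoxc13 to Hoxc4. HoxA on chromosome 6 (52143394 to 52328670) spanned 185.3 kb with 14 genes, HoxB on chromosome 11 (96226506 to 96388784) 162.3 kb with 9, and HoxD with Evx2 on chromosome 2 (74637251 to 74773240) 136.0 kb with 11. On chromosome 7, domains of 128.5 and 127.7 kb held the 5′ ends of Rhcg, an ammonium transporter gene, and Nr2f2, a nuclear receptor gene.

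The other 4 of the 10 widest lay on the X chromosome. Domains of 190.9 kb (99475260 to 99666201) and 126.0 kb (99138411 to 99264454) held no protein-coding 5′ end, and those of 127.0 and 125.5 kb held Tmsb4x, an actin-sequestering peptide gene, and Tsc22d3, a glucocorticoid-induced gene. The X domain of 190.9 kb was made of 132 peaks, compared with 47 in the wider HoxC domain. In all there were 2038 domains of at least 10 kb, 463 of them (22.7%) on X, and 100 of at least 50 kb. With the pooled list there were 3348, 205 of them of at least 50 kb, and when gaps of up to 1 kb were joined 1016, with 139 on X (13.7%) and 21 of at least 50 kb. Joining gaps of up to 5 kb gave 201 of at least 50 kb, and leaving out X gave 61.

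**Figure D2:**
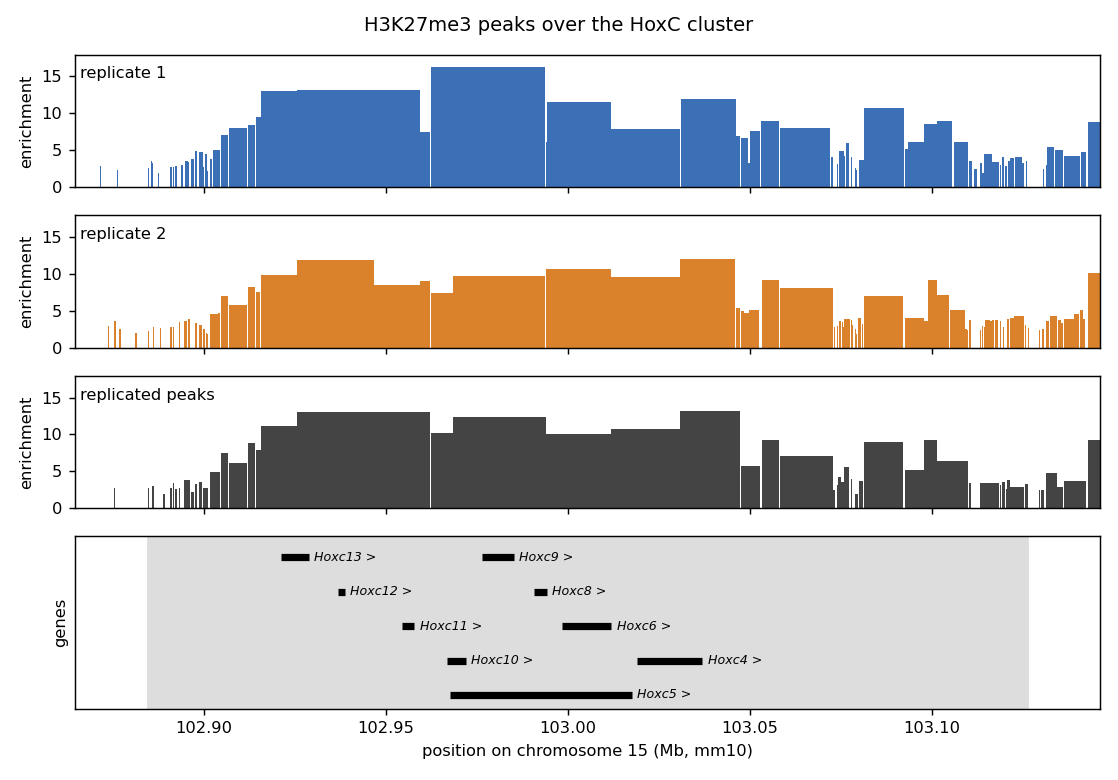
Peaks of replicate 1, replicate 2 and the replicated list over the HoxC cluster on chromosome 15 (horizontal axis, position in Mb on mm10), drawn as bars from 0 to the enrichment given by the authors, with protein-coding genes below as lines and arrows for their strand. The grey band is the domain of 241.7 kb, in which all 9 genes are marked.

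Chromosomes were then compared for the share of their length covered. The X chromosome stood first, with 4.78% covered by replicated peaks against a median of 1.98% and a maximum of 3.30% over the 19 autosomes, a ratio to the median of 2.41 (exact permutation p = 0.05, the smallest that 20 chromosomes allow). Promoters on X were also marked most often. Of 948 X-linked genes 343 (36.2%) were marked, including Tmsb4x, covered over 92.8% ± 10.2, and Tsc22d3, over 89.0% ± 3.15 (SD, n = 2). On the autosomes 4357 of 20780 genes were marked.

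The replicates differed in this respect by more than on any autosome. Replicate 2 covered 5.87% of X and replicate 1 covered 3.46%, a ratio of 1.70, whereas on the autosomes the ratio of replicate 2 to replicate 1 lay between 0.884 and 0.911. In replicate 1 alone X ranked 2 of 20 with 1.58 times the autosomal median (exact permutation p = 0.1), so the first rank was not reached without replicate 2. Of the peaks, 21.6% in replicate 2 and 13.6% in replicate 1 were on X.

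**Figure D3:**
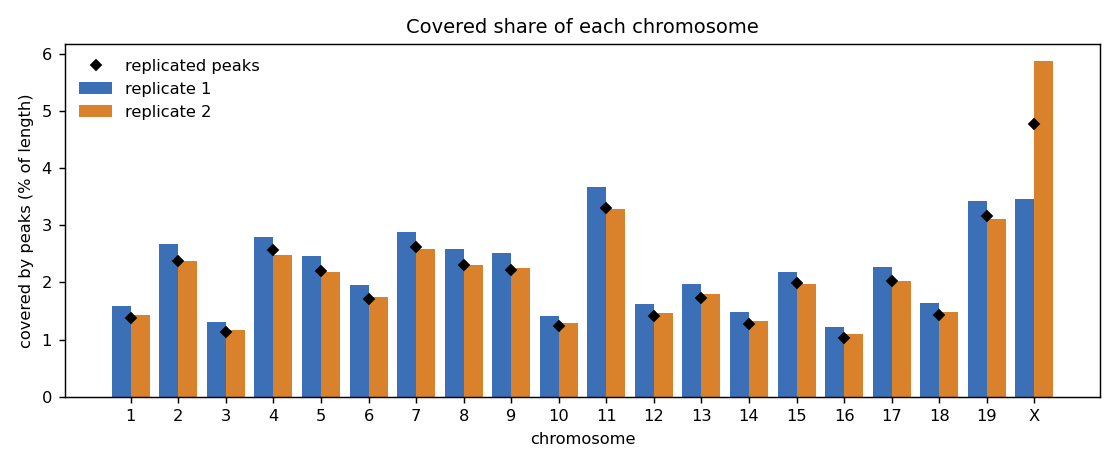
Percentage of each chromosome covered by peaks (vertical axis) for chromosomes 1 to 19 and X (horizontal axis), with bars for each replicate and diamonds for replicated peaks. Replicate 1 lies slightly above replicate 2 on every autosome, and on X replicate 2 reaches 5.87% against 3.46%.

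Positions of the peaks relative to genes were compared with shifted positions. Of replicated peaks 9.48% came within 1 kb of a protein-coding 5′ end, against a mean of 2.27% after shifts, a ratio of 4.17 (permutation p = 0.002, the smallest that 1000 shifts allow two-sided). By midpoint, 6.02% lay in promoter windows, 5.62% in exons, 36.4% in introns and 52.0% outside genes, against 1.60, 3.24, 35.0 and 60.2% after 100 shifts. X-linked peaks lay in introns in 42.6% of cases (24.9% after shifts), autosomal peaks in 34.6% (37.5% after shifts).

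Marked promoters were richer in CpG dinucleotides than unmarked ones. The median observed/expected CpG ratio was 0.531 at marked and 0.442 at unmarked genes, a difference of 0.0893 (permutation p = 1e-05, the smallest that 100000 resamples allow). The relation was not steady. Genes with a ratio of 0.4 to 0.6, such as Myod1 with 0.535 and Neurog3 with 0.517, were marked most often (33.9%, 95% Wilson interval 32.6 to 35.3%). Below 0.2 the share was 6.37%, and at 0.8 or more, as at Bmi1 with 0.989, it was 17.4% (15.8 to 19.3%). The upper quartile of the ratio was 0.661 for marked and unmarked genes alike.

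**Figure D4:**
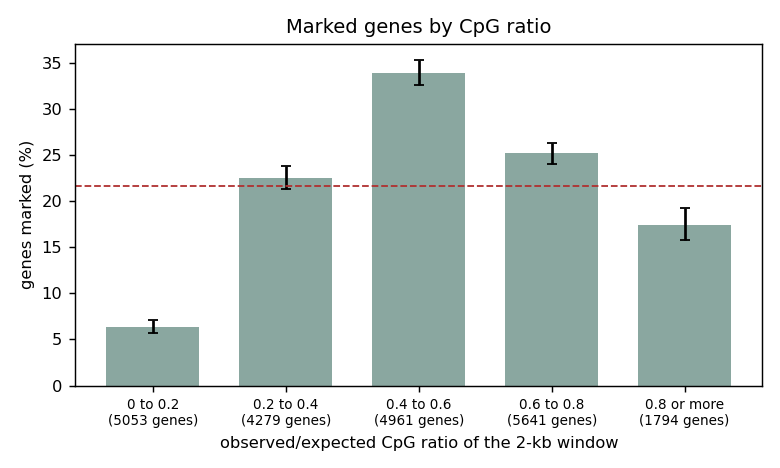
Percentage of genes marked (vertical axis) by the observed/expected CpG ratio of the 2-kb window (horizontal axis), with the number of genes in each bin and 95% Wilson intervals as error bars. The dashed line is the 21.6% of all genes, and the bin from 0.4 to 0.6 is highest at 33.9%.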

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

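The omission of chromosome X was chosen after seeing the data, and all other alternatives were planned. Shares of replicate peaks shared, the promoter share of peaks and the CpG difference kept direction and call under every alternative run. With the stricter list the counts were 46294 peaks in replicate 1, 48188 in replicate 2 and 66959 pooled, and 78.1% of that pooled list were replicated. Of all pooled peaks 48.8% were replicated, and 46.8% when X was left out. Marked genes fell to 2978 with at least 50% of the window covered. Wide domains numbered 3348 with the pooled list and 1016 with gaps of up to 1 kb. The covered share of X ranged from 3.46% to 5.87% over the single replicates and ranked 2 of 20 in replicate 1 alone. Counting neighbours once left 19 lists above, all among the original 29, in a smaller set of genes with a higher background share, and added 3 calls below (Polycomb complex, proteasome and cytochrome P450 genes). The pooled list added 3 calls (keratins above, proteasome and cytochrome P450 genes below). Limiting the test to CpG-rich promoters ended 7 calls (cartilage and bone, skeletal muscle, Dlx, Six-family, claudins, vomeronasal receptors and serpins) and added 3 (blood and cytochrome P450 genes above, proteasome below). Lists left with no gene at that ratio were not tested, and others had fewer members, so a call lost there need not reflect CpG content. Requiring at least 50% of the window covered ended the calls for cartilage and bone and NADH dehydrogenase genes and added imprinted genes. A window of 2.5 kb ended that for Six-family genes and added 2 below (proteasome and cytochrome P450 genes). Apart from solute carriers with neighbours counted once (34.7% marked, adjusted p = 0.245, Fisher's exact test), each list that changed sides had not passed the test originally. Pluripotency and germline genes were marked in 22.2 to 29.6% over single replicates, 29.6% at 2.5 kb, 14.8% with at least 50% of the window and 25.9% at any start. Polycomb genes were at 19.4 to 25.8% over single replicates, 32.3% at 2.5 kb, 19.4% at 0.5 kb and 32.3% at any start. Cell cycle inhibitors were at 25% (pooled), 18.2% (neighbours once) and 20.0% (CpG-rich). Liver-secreted proteins were at 30% (2.5 kb), 25% (any start) and 100% (CpG-rich). Keratins were at 6.12% (50% of the window), blood genes at 34.8% (neighbours once) and cytochromes P450 at 66.7% (CpG-rich, adjusted p = 0.0412, Fisher's exact test). The share of the other genes also changed with the setting, so a list could change sides while its own share stayed the same. Cell cycle inhibitors, for example, were at 25% originally and with the pooled list, and Polycomb genes at 19.4% originally and at 0.5 kb. The cause was not otherwise tested, and several of these shares rest on very few genes. Sequencing depth was unknown, so missing peaks cannot be separated from peaks too weak to call.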

Other observations

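The families by symbol prefix and the comparison of gene bodies with the rest of each chromosome were chosen only after the results were seen. So were the CpG-limited escape gene comparison, the check of the floor under called peaks and the test of overall depth. Among 442 symbol prefixes with at least 6 genes, 23 were marked more often and 7 less often than other genes (Fisher's exact test, adjusted over the 442). Synaptotagmin genes, which encode calcium sensors of vesicle release, were marked in 14 of 17 cases (adjusted p = 7.41e-05), and serotonin receptor genes in 12 of 14 (adjusted p = 0.000134, Fisher's exact test). Examples were Syt2, covered over 98.6% ± 2.05, Syt7 over 84.8% ± 2.26 and Htr1a over 90.5% ± 0.990 (SD, n = 2). All 6 Armcx genes, a cluster on the X chromosome, were marked (adjusted p = 0.00753, Fisher's exact test), Armcx2 over 25.5% in replicate 1 and 78.5% in replicate 2, but the test set them against all genes, while 36.2% of X-linked genes were marked, and neighbours were not counted once for any prefix. By contrast 0 of 49 mitochondrial ribosomal protein genes of the Mrpl prefix (adjusted p = 0.00133), 0 of 38 taste receptor genes (0.0126) and 0 of 34 Rhox homeobox genes, a reproductive cluster on X (0.0223), were marked by Fisher's exact test.

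Gene bodies on X were covered over 8.93% by replicated peaks and the rest of X over 3.29%, a ratio of 2.71. On the autosomes the median ratio was 1.57, with a range of 0.944 to 2.27 (exact permutation p = 0.05, the smallest possible with 20 chromosomes). Both replicates had this order, with ratios on X of 2.65 and 2.72 against autosomal medians of 1.49 and 1.48. Among genes with a CpG ratio below 0.3, 12 of 1127 olfactory receptor genes and 712 of 6438 others were marked, an odds ratio of 0.0866 (p = 7.94e-37, Fisher's exact test). A ratio below 0.3 was thus not enough to account for the low share of the receptors. Ratios were not matched within that group. Over all genes, the marked share was 6.37% below 0.2 and 22.5% from 0.2 to 0.4. Differences in CpG content below 0.3 therefore stay open, and neighbouring receptors were not counted once.

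The X chromosome was covered more in replicate 2 than in replicate 1. Overall depth or a looser threshold in replicate 2 was argued against by the autosomes, where the median ratio of covered shares was 0.897. A factor common to all X values, such as a control or copy number that differed between pools, would shift strong and weak X peaks alike, and the log2 shift was greater by 0.0787 in the strongest 1052 of 10244 X peaks (95% bootstrap interval 0.0568 to 0.106). This met the criterion set in advance against that factor, but the criterion was wrong because enrichment is known only for called peaks: a single factor applied to autosomal peaks with a floor gave a difference of 0.0968, so the factor cannot be told apart from an uneven change. A different proportion of female embryos in the pools may also be involved and was not tested, since the labels call both pools mixed.

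X was also covered more than the autosomes when both replicates were combined. Marked X promoters alone were argued against by peaks over 10 kb from any protein-coding 5′ end, which covered 3.74% of X compared with a median of 0.897% over the autosomes, all of which lay below X. A candidate explanation is the inactive X of the female embryos, for which 7 genes listed beforehand as escaping inactivation were to be covered less than other X genes. Their median covered share over gene body and 5-kb flanks lay 1.67 percentage points above that of the 941 other genes (permutation p = 0.353, two-sided), where their median of 0 allowed no lower value, and in replicates 1 and 2, with medians of 0.427 and 1.24 in the others, escape genes were also higher, by 0.642 and 3.85 (permutation p = 0.423 and 0.305), against the predicted direction but within the spread of so few genes. Limiting both sides to a CpG ratio of at least 0.4, after that result was seen, left 5 escape genes and 390 others and turned the differences to the predicted direction. They were −3.03 in the replicated list, −3.92 in replicate 1 and −6.69 in replicate 2 (permutation p = 0.659, 0.347 and 0.529), again within the spread of so few genes. In the replicated list the median of the escape genes fell from 1.67% to 1.24%, while that of the others rose from 0 to 4.27%. The direction thus depended on which genes were kept, so these comparisons cannot decide and the hypothesis stays open.

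Most transcription factor genes of the facial mesenchyme carried peaks although the tissue is facial. Weak calls near the threshold were argued against, since 89.1% of the list was also marked in the stricter list. A hypothesis is that the mark lies in only part of the cells, as in a tissue of several territories and cell types. It predicts a lower median enrichment of this list than of the central nervous system list. The median over marked genes was lower, with 5.85 (41 genes) against 9.15 (57 genes), a difference of −3.30 (permutation p = 1e-05, the smallest possible). This comparison cannot decide, because among the lists tested only Hox and Gata genes had a median above 9.15. Medians were lower for lists of cell types present in part of the tissue (3.33 for cartilage and bone, 4.85 for skeletal muscle, 6.80 for epithelium, 7.07 for endothelium). They were also lower for lists not chosen for such cell types (5.81 for GABA and glutamate receptors, 6.55 for potassium channels). The same held for endoderm and kidney factors (8.24) and for heart and limb factors (8.55). Lower enrichment could equally come from less of the mark in every cell, which peak lists cannot separate, and no biological explanation could be tested across groups because the design had 1.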
